A study of Drosophila melanogaster with 2 samples.

How the data were processed

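Posterior midguts of 9-day-old female Drosophila melanogaster were profiled by poly(A) RNA sequencing in 2 conditions, induced and uninduced Gli-RNAi. The flies carried 5966GS-GAL4, a GeneSwitch driver that is active in enterocytes only when the steroid RU486 is given, and a UAS transgene that makes double-stranded RNA against Gli (gliotactin). Per the labels' protocols, RU486 induced the RNAi and ethanol alone served the control, 75 midguts were dissected per condition, and 3 libraries were made per condition. The labels call these biological replicates and also say that midguts were pooled at RNA extraction, so the p-values given here measure the spread between libraries, which may be partly technical. Drug and knockdown come together in this design: a driver line without the RNAi transgene on RU486 was not analysed here, so an effect of RU486 itself cannot be separated from that of the knockdown.

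The deposited transcript table gives, per the file headers, raw read counts for each of 24047 transcripts in each of the 6 libraries, with the authors' normalised signal, p-values and adjusted p-values. Per the submitters' processing notes DESeq was used. The aligner, the counting program, the strand setting and the genome build are not given in the sources used here. A read in an exon shared by several transcripts of a locus was counted in each of them in the deposited counts, since the sum over all transcript rows was 1.998 times the sum with 1 transcript per locus. The authors' signal is, per the file headers, a constant times the reads in a transcript divided by all mapped reads and by transcript length, and was used here only to work out the total of mapped reads. The second deposited table lists 3049 genes with the mean log2 fold change over a gene's transcripts and a smallest p-value, both as computed by the authors. Its log2 values run induced over uninduced, as the deposited read counts show, although the column description of the transcript table gives the opposite order. Its p-value column holds adjusted p-values of the transcript table for most genes. Symbols of 7 loci in the transcript table have the form of dates, as a spreadsheet writes them, and were replaced through their Entrez identifiers.

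The transcript with the highest mean count stood for each of the 13822 loci, of which 11298 had a read in any library. Symbols were updated through the Entrez identifier with the RefSeq gene table of release 6, which matched 12825 loci. Coordinates are printed only as the deposited table gives them, in a build that the table does not name. On chromosome 2L 88.4% of the loci lay inside the release 6 position of the same gene, and on 2R 0 of 2596 did, so the table does not use release 6 throughout. Names of 362 loci are shared by several genes, which held 3.82% of the reads, and such loci are given as uncertain where they are named. Members of families of near-identical genes (the Lys lysozymes, Hsp70, the Jonah proteases) may share reads and are likewise uncertain one by one.

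Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter on low expression and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The filter left 8236 genes. Normalised counts are reads divided by a scaling factor with a mean of 1 over the libraries, values after ± are SD over 3 libraries for counts and SE for log2 fold changes, and log2 fold changes are induced minus uninduced. The SE was the absolute log2 fold change divided by the square root of F. A total of 36 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the residuals. Counts of list members past the threshold are over all genes tested, with counts adjusted over the list alone beside them. For a gene with 0 reads in all libraries of a condition, the fold was bounded with a floor of 3 reads over the condition, and with 1 to 3 reads the ratio of scaled totals is given with its exact (Clopper-Pearson) 95% counting interval. Such intervals and floors cover counting error only.

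Named genes followed a rule fixed beforehand. Gli came first, followed by the 10 genes that rose and the 10 that fell with the largest absolute log2 fold change among those past the threshold, with at least 50 normalised counts in the higher condition and no overlap between the libraries of the 2 conditions. From each list at most 4 members past the threshold with the largest absolute log2 fold change and at most 2 members not past it with the highest mean could be named, and upd3, vn, Krn, upd2, Delta, esg, nub and pros were always given where measured. Genes named outside the rule are said to be so.

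The procedure was tested on simulated counts for 8236 genes with the libraries' depths, in which 50 genes were changed at each of 4 sizes. It recovered 42% of the genes changed 1.25-fold, 80% of those changed 1.5-fold, 88% of those changed 2-fold and 98% of those changed 4-fold, with 4 false calls in all. The alternatives were DESeq2 1.42.0 size factors and its Wald test, limma-voom, no filter, a mean of at least 50 counts, leaving out each library in turn, the replicate number as a block, other thresholds, and, chosen after seeing the data, library totals or upper quartiles as scaling, sums over transcripts for the gene counts, and omission of mitochondrial and shared loci. For the gene lists the estimated correlation, the mean of at least 50 counts, the sums over transcripts and the replicate block were planned, and the other settings were chosen after seeing the data. Alternatives for tables without counts (pseudocounts, Fisher's exact test of a called list) did not apply.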

Results

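RNA was sequenced from posterior midguts of female flies in which Gli-RNAi had been induced in enterocytes with RU486 and from uninduced controls given ethanol, in 3 libraries each. Gli encodes gliotactin, a transmembrane protein of the junctions where 3 epithelial cells meet, and the comparison asks which transcripts of the gut differ once it is depleted from enterocytes, the absorptive cells of the gut. Counted with 1 transcript per locus, the induced libraries held 14303722, 8111031 and 10032003 reads and the control libraries 7319238, 10914491 and 6821908. Mitochondrial transcripts took between 6.60% and 8.60% of the reads of a library.

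Gli itself was read first in every library. Its normalised count was 882, 895 and 920 in the induced libraries and 2066, 1973 and 1847 in the controls, a mean of 899 ± 19.1 against 1962 ± 110 (SD, n = 3). Gli fell by 1.13 ± 0.059 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 1.2e-09), which is 2.18-fold. The transcript counted runs from 15756001 to 15762755 on the minus strand of chromosome 2L, in the unnamed build of the deposited table, and has 8 exons. The whole dissected tissue was sequenced, so Gli transcripts of cells other than enterocytes are part of this count.

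**Figure D1:**
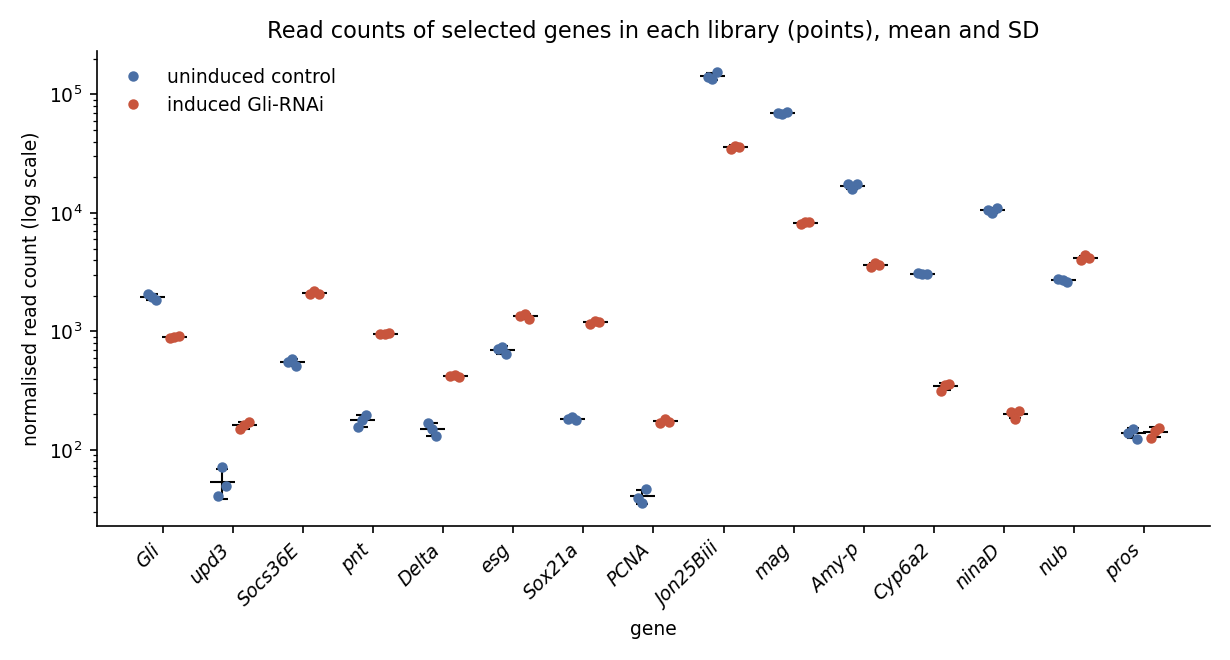
Normalised read counts (log axis) of 15 genes named in the text, with a point for each of the 3 control and 3 induced libraries, and the mean and SD as black bars. Gli lay between 882 and 920 in the induced libraries and between 1847 and 2066 in the controls, while pros had a mean of 142 ± 13.8 against 139 ± 13.6.

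Induction of Gli-RNAi went with widespread change. Of 8236 genes tested, 2272 rose and 2204 fell, and 457 of the rising and 613 of the falling genes changed at least 2-fold. Genes of progenitor cells, of cell division, of the EGFR, JNK and JAK/STAT pathways and of cell junctions were among those that rose, and genes of digestion, detoxification and protein synthesis were among those that fell. The first principal component of 6838 genes with a mean of at least 50 counts held 91.5% of the variance and separated the conditions. Correlations between libraries lay at 0.997 within the induced condition, between 0.991 and 0.996 within the controls and between 0.920 and 0.929 across conditions, all over genes, which are not independent replicates. The common coefficient of variation beyond counting error was 0.0276 within the induced condition and 0.0786 within the controls. The test pooled the 2 conditions in its dispersions, so the p-values do not reflect this difference in spread. Control replicate 3 stood apart from the other controls on the second component (4.57% of the variance), and without it 2466 genes rose and 2492 fell. With library totals as scaling, chosen after seeing the data, the median over all genes moved up by 0.19 (log2) and 3737 genes rose against 1512 that fell (71.2% against 50.8% rising), so that directions of small changes are relative to the scaling.

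Several of the genes with the largest changes were near absent in one of the conditions. CG34324 had 0 reads in the controls and a normalised count of 3183 ± 111 in the induced libraries, at least 2554-fold higher, and CG31077 had 0 reads in the controls and 98.0 ± 8.35, at least 78.2-fold higher. Muc68D, a mucin gene, rose from 5.14 ± 1.68 to 876 ± 10.98, CG3906 from 2.39 ± 2.89 to 658 ± 22.045, CG14125 from 2.86 ± 1.32 to 471 ± 6.38 and CG14645 from 5.82 ± 2.84 to 783 ± 35.98. CG7567 rose from 6.02 ± 1.60 to 576 ± 4.65 and CG34220 from 35.6 ± 5.22 to 2968 ± 120. CG6839 had 2 control reads and 529 induced reads, a ratio of scaled totals of 179 (95% interval 49.4 to 1484), and Hsp70Bb, a heat shock gene with near-identical copies whose reads cannot be assigned with certainty, had 3 and 505 (ratio 114, interval 38.8 to 555).

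In the other direction CG34215 had 482 control reads and 1 induced read, a ratio of 711 (95% interval 127 to 28145). The cytochrome P450 gene Cyp4p2 fell from 610 ± 12.2 to 3.69 ± 2.65 and lectin-24A, a C-type lectin, from 1324 ± 106 to 11.98 ± 2.75. The scavenger receptor gene ninaD, which serves carotenoid uptake, was the most abundant of the 10 and fell from 10559 ± 502 to 202 ± 17.2, which is 51.8-fold. The lysozyme genes LysD, LysC and LysB fell, with log2 fold changes of -6.35 ± 0.303, -5.89 ± 0.233 and -5.33 ± 0.379, although these near-identical genes may share reads. CG9993, CG16713 and antr completed these 10, with log2 fold changes of -5.47, -5.03 and -5.00. All these adjusted p-values were 3.3e-08 or lower.

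Genes of septate junctions, the barrier between gut epithelial cells, rose more often than they fell. Of 28 tested members 15 rose and 1, Gli, fell, and the counts adjusted over the list alone were 15 and 1 (median log2 fold change 0.40, camera adjusted p = 0.0107). The number that fell was 2 with the replicate block, with sums over transcripts, and without control replicate 2, control replicate 3 or induced replicate 3. The list call was lost at an adjusted p = 0.151 with an estimated correlation. Nrg rose from 233 ± 9.32 to 649 ± 26.1, M6, which encodes a protein of tricellular junctions, from 436 ± 6.30 to 980 ± 55.2, and cora from 2197 ± 359 to 4567 ± 177. The smooth septate junction genes mesh, Ssk and Tsp2A, named after their values were seen, rose by 0.88 ± 0.061, 0.66 ± 0.052 and 0.77 ± 0.065. Atpalpha (log2 fold change -0.12, adjusted p = 0.20) and scrib (0.22, adjusted p = 0.23) did not pass the test. Among 12 adherens junction and polarity genes 8 rose and 0 fell (list alone 8 and 0), led by shg, which encodes E-cadherin, at 1.08 ± 0.132 and baz at 0.78 ± 0.102, while aPKC (-0.04) and crb (0.12) did not pass, and the list itself did not pass camera (adjusted p = 0.106, or 0.0158 with limma-voom, 0.0461 without the filter and 0.0498 without control replicate 3).

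Several ligand and target genes of pathways that act in gut repair rose. The cytokine gene upd3 rose from 53.9 ± 15.7 to 162 ± 11.4, the feedback inhibitor gene Socs36E from 549 ± 36.7 to 2107 ± 67.7 and the receptor gene dome from 714 ± 59.0 to 1307 ± 80.7. Of 7 tested JAK/STAT genes 4 rose and 0 fell (list alone 4 and 0, camera adjusted p = 0.0110, adjusted p = 0.369 with an estimated correlation), and Stat92E (0.08) and hop (0.08) did not pass. The cytokine gene upd2 was below the filter, with 28 induced and 8 control reads. All 8 tested EGFR ligand and target genes rose (list alone 8, median 1.01, camera adjusted p = 1.4e-04, adjusted p = 0.1005 with an estimated correlation). The transcription factor gene pnt rose from 178 ± 21.4 to 961 ± 13.2, the feedback inhibitor gene sty from 963 ± 29.5 to 2786 ± 71.6 and the ligand gene vn from 43.8 ± 9.41 to 78.3 ± 4.45. Krn could be read only in a locus that it shares with CG32177, at 529 ± 11.4 in the controls and 583 ± 45.7 in the induced libraries (adjusted p = 0.13).

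Of 13 JNK, wound and apoptosis genes 10 rose and 2 fell (list alone 10 and 2, median 0.47, camera adjusted p = 8.6e-04, adjusted p = 0.1005 with an estimated correlation). With library totals as scaling 10 of them rose and 0 fell. The matrix metalloprotease gene Mmp2 rose from 72.3 ± 6.62 to 640 ± 47.6 and Mmp1 from 1680 ± 56.6 to 2990 ± 69.8, the transcription factor genes Ets21C and kay rose by 1.21 ± 0.122 and 1.04 ± 0.049, and the JNK phosphatase gene puc, named after its value was seen, by 0.57 ± 0.052. In the list of Notch, Wnt, Hippo, BMP and hedgehog genes 6 of 11 rose and 3 fell (list alone 6 and 4, camera adjusted p = 0.335), or 7 rose and 1 fell with library totals as scaling. The receptor gene N rose by 1.40 ± 0.102 and ptc by 0.93 ± 0.105, and Notum, a Wnt antagonist, fell by 1.17 ± 0.209.

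Most tested markers of intestinal progenitors (stem cells and enteroblasts) and most cell cycle genes rose. Of 13 tested progenitor genes 11 rose and 1 fell (list alone 11 and 1, median 1.497, camera adjusted p = 1.5e-06, adjusted p = 0.1005 with an estimated correlation). Sox21a rose from 184 ± 5.49 to 1199 ± 32.9, the stem cell ligand gene Delta from 150 ± 19.2 to 424 ± 8.64, the progenitor transcription factor gene esg from 701 ± 49.6 to 1338 ± 69.9, E(spl)m3-HLH from 103 ± 10.5 to 381 ± 15.8 and sna from 11.7 ± 3.83 to 69.5 ± 7.60. Su(H) did not pass (0.14, adjusted p = 0.58). Of 30 cell cycle genes 27 rose and 1 fell (list alone 27 and 3, median 1.55, camera adjusted p = 2.2e-05, adjusted p = 0.1005 with an estimated correlation). In several other settings 2 of them fell: DESeq2 size factors, the DESeq2 Wald test, limma-voom, upper quartiles and sums over transcripts. The same held without mitochondrial and shared loci, without control replicate 1 and without control replicate 3. With library totals as scaling 0 fell. The mitotic genes borr, pav, aurB and feo rose by 2.64 ± 0.372, 2.60 ± 0.277, 2.28 ± 0.242 and 2.25 ± 0.245 from control counts of 12.2 or less, and PCNA, the replication clamp gene, named after its value was seen, rose from 40.5 ± 5.70 to 174 ± 6.78. E2f1 (-0.16, adjusted p = 0.052) and tum (-0.28, adjusted p = 0.067) did not pass.

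Enteroendocrine genes fell more often than they rose. Of 19 tested, 3 rose and 11 fell (list alone 3 and 11), though the list did not pass camera (adjusted p = 0.106, or 0.0356 with limma-voom). The transcription factor gene tap fell by 2.03 ± 0.338, and the peptide hormone genes CCHa2, NPF and Orcokinin fell, at -1.77 ± 0.077, -1.03 ± 0.096 and -0.93 ± 0.175. The class marker pros had a count of 139 ± 13.6 in the controls and 142 ± 13.8 in the induced libraries, and AstA (0.07) and Dh31 (0.16) did not pass either. Of 12 enterocyte identity genes 4 rose and 3 fell, or 6 fell without control replicate 3 (list alone 4 and 4, camera adjusted p = 0.189). The median (-0.11), the mean (0.19) and the camera direction (up) differed in sign, and the median was 0.08 with library totals as scaling. The transcription factor gene nub rose from 2695 ± 84.7 to 4193 ± 172, Mur29B rose by 2.40 ± 0.049, and Npc1b, a gene of sterol absorption, fell by 1.03 ± 0.052. Myo31DF (0.06) and cad (-0.12) did not pass.

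Most tested enzymes of carbohydrate and lipid digestion fell. Of 24 such genes 22 fell and 0 rose (list alone 22 and 0, median -1.4965, camera adjusted p = 2.6e-29, adjusted p = 0.1005 with an estimated correlation). The lipase gene mag fell from 69813 ± 1520 to 8292 ± 135 and the amylase gene Amy-p from 17012 ± 953 to 3613 ± 141, while the mannosidase genes LManII (-0.09) and LManVI (0.06) did not pass. The list's share of all reads was 2.62% ± 0.0647 in the controls and 1.36% ± 0.0221 in the induced libraries. Digestive serine proteases changed in both directions. Of 29 tested, 18 fell and 8 rose (list alone 18 and 8, camera adjusted p = 1.7e-04, adjusted p = 0.506 with an estimated correlation). Jon25Biii, at 142990 ± 9748 the most abundant of those named, fell to 36089 ± 1064, Jon44E fell by 4.32 ± 0.074 and Jon65Aii fell by 1.92 ± 0.056, whereas Jon66Cii rose from 342 ± 31.8 to 2149 ± 68.9, and Jon65Aiv (-0.07) and alphaTry (-0.06) did not pass. Of 5 lysozyme genes 4 fell and 1, LysX, rose, from 377 ± 31.7 to 1903 ± 57.1 (list alone 4 and 1, camera adjusted p = 0.0647, or 0.0148 with sums over transcripts, 0.0272 with library totals, 0.0337 with the replicate block, 0.0332 without control replicate 1, 0.0260 without induced replicate 2 and 0.0221 without induced replicate 3). The lysozyme list's share of all reads nevertheless rose, from 0.00723% in the controls to 0.0212% in the induced libraries. Of 13 genes of mucins, chitinases and the peritrophic matrix 8 rose and 3 fell (list alone 9 and 3, camera adjusted p = 2.2e-05, adjusted p = 0.1005 with an estimated correlation), with Cht8 at 3.51 ± 0.242, Cht2 at 3.23 ± 0.277 and Muc68D as above.

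Several markers of neighbouring tissues fell as well. Of 8 tested genes listed for Malpighian tubule and hindgut 6 fell and 1 rose (list alone 6 and 1, median -1.34, camera adjusted p = 0.0828, or 0.0257 with limma-voom, 0.0359 with sums over transcripts, 0.0395 with library totals, 0.0399 with the replicate block, 0.0461 without the filter, 0.0475 without control replicate 1, 0.0437 without induced replicate 2 and 0.0497 without induced replicate 3). The one that rose, DnaJ-1, named after its value was seen, is also in the heat shock list and was the most abundant of them, at 794 ± 42.9 in the controls and 1239 ± 56.6 in the induced libraries, and the list's share of all reads was 0.01385% in the controls and 0.01616% in the induced libraries. Of the others Irk2 fell from 284 ± 36.6 to 53.7 ± 1.42, Uro, which encodes urate oxidase, from 55.9 ± 9.87 to 11.9 ± 3.74 and the hindgut transcription factor gene byn from 35.001 ± 6.06 to 11.1 ± 1.13. Of 7 fat body genes 5 fell and 1 rose, or 0 rose without induced replicate 3 (list alone 5 and 1, camera adjusted p = 0.00214, adjusted p = 0.155 with an estimated correlation), and the yolk protein genes Yp1 and Yp3 fell, at -1.46 ± 0.059 and -1.75 ± 0.076. Of the 5 genes listed for the copper cell region, the acidic middle segment of the midgut, 4 fell and 1 rose (list alone 4 and 1, camera adjusted p = 0.618). CAH7, lab and Vha100-4 fell, at -1.20 ± 0.096, -0.92 ± 0.116 and -0.59 ± 0.057, and the gene that rose, Mur29B, is also in the enterocyte and mucin lists. The median (-0.59) and mean (-0.11) of that list were negative, while its camera direction was up.

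Among the remaining tissue lists none passed camera in the main setting. Of 17 visceral muscle genes 5 rose and 3 fell (list alone 6 and 4, adjusted p = 0.305). The number that fell was 6 without control replicate 3, 1 without control replicate 2 and 0 without induced replicate 2 or induced replicate 3. Zasp52 rose by 1.48 ± 0.070 and Mlc2 (-0.09) did not pass. With library totals as scaling 9 rose and 0 fell, and the median of this list turned from -0.04 to 0.15. Basement membrane genes rose in 5 of 8 and fell in 0 (list alone 5 and 0, adjusted p = 0.106, or 0.0313 with limma-voom and 0.0384 without control replicate 3), led by LanA at 1.14 ± 0.122. Tracheal genes rose in 4 of 8 and fell in 1, or in 0 without control replicate 2 (list alone 4 and 1, adjusted p = 0.337), haemocyte genes rose in 1 of 3 and fell in 1 (list alone 1 and 1, adjusted p = 0.667), germline and eggshell genes rose in 4 of 6 and fell in 1 (list alone 4 and 1, adjusted p = 0.618; 2 rose without control replicate 1 or induced replicate 2, and 1 with the DESeq2 Wald test) and genes of anterior gut, crop and salivary gland rose in 1 of 5, or in 2 without control replicate 2, and fell in 2 (list alone 2 and 2, adjusted p = 0.323). The one that rose in the main setting in the last of these, pdm2, went from 163 ± 19.0 to 725 ± 28.9.

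Few antimicrobial peptide genes were detected. Of 18 members 16 were below the filter, with 55 induced and 38 control reads over all of them together. Drsl2 had 74 induced reads and 1 control read (ratio 50.2, 95% interval 8.73 to 2008) and Drsl3 rose by 1.78 ± 0.407 (list alone 2, camera adjusted p = 0.315). Of 23 genes of the Imd and Toll pathways 3 rose and 8 fell (list alone 3 and 8, camera adjusted p = 0.215). The peptidoglycan recognition protein genes PGRP-SC1a, PGRP-SC1b and PGRP-SC2 fell, at -2.66 ± 0.198, -2.30 ± 0.192 and -1.35 ± 0.050, and PGRP-SC2 was the most abundant of them at 13429 ± 676 in the controls. The NF-kB gene Rel (-0.05) and PGRP-LB (-0.07) did not pass.

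Most tested cytochrome P450 genes fell. Of 42 such genes 33 fell and 5 rose, or 3 rose without control replicate 2 (list alone 34 and 5, median -1.23, camera adjusted p = 4.8e-19, adjusted p = 0.1005 with an estimated correlation). With library totals as scaling 31 of them fell and 8 rose. Cyp6a2 fell from 3062 ± 51.1 to 344 ± 23.7 and Cyp28d1 from 1691 ± 46.1 to 156 ± 16.3, while Cyp6a23, at 14832 ± 806 in the controls, did not pass (0.01, adjusted p = 0.88). Of 34 glutathione S-transferase and UDP-glycosyltransferase genes 20 fell and 3 rose (list alone 20 and 3, camera adjusted p = 1.8e-04, adjusted p = 0.270 with an estimated correlation), with Ugt37B1 at -3.79 ± 0.136 and GstD3, which rose, at 1.87 ± 0.238. With library totals as scaling 19 of these fell and 10 rose. Of 18 redox genes 12 fell and 2 rose (list alone 12 and 2, camera adjusted p = 0.00675, adjusted p = 0.128 with an estimated correlation), and the glutathione synthesis gene Gclm, the catalase gene Cat and Keap1 fell, at -1.24 ± 0.059, -1.16 ± 0.054 and -1.15 ± 0.084. Among the redox genes 9 fell and 4 rose with library totals as scaling. Heat shock genes rose in 8 of 9 and fell in 0 (list alone 8 and 0, camera adjusted p = 3.7e-04, adjusted p = 0.128 with an estimated correlation), with Hsp23 at 2.13 ± 0.144, Hsp68 at 1.60 ± 0.123 and Hsp83 at 0.76 ± 0.046.

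Ribosomal protein genes fell and most proteasome genes rose. All 77 tested cytoplasmic ribosomal protein genes fell (list alone 77, median -0.64, camera adjusted p = 1.0e-17, adjusted p = 0.369 with an estimated correlation), and 76 of them fell with library totals as scaling, at a median of -0.45. RpS29 fell from 11832 ± 230 to 5656 ± 441. Of 31 proteasome genes 29 rose and 0 fell (list alone 29 and 0, median 0.33, camera adjusted p = 0.00179, adjusted p = 0.369 with an estimated correlation), with Rpt4 at 0.51 ± 0.064. Vacuolar ATPase genes rose in 4 of 20 and fell in 5 (list alone 4 and 5, camera adjusted p = 0.812), or rose in 11 and fell in 2 with library totals as scaling. Of 13 endoplasmic reticulum stress genes 6 rose and 5 fell (list alone 6 and 5, camera adjusted p = 0.841), with Gp93 at 0.58 ± 0.046 and Ire1 at -0.47 ± 0.090.

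Among metabolic genes, 15 of 22 for lipid and sterol handling fell and 1, Npc2a, rose, or 2 rose when any one control library was left out and without induced replicate 1 (list alone 15 and 1, camera adjusted p = 0.00151, adjusted p = 0.128 with an estimated correlation). With library totals as scaling 12 of them fell and 4 rose. The lipophorin receptor gene LpR1 fell from 934 ± 20.5 to 228 ± 14.9, the triglyceride synthesis gene mdy fell by 1.78 ± 0.117, and SREBP (0.10) did not pass. Glycolytic genes fell in 11 of 13 and rose in 2 (list alone 11 and 2, camera adjusted p = 0.189, or 0.0130 with limma-voom and 0.0498 without control replicate 3), and with library totals as scaling 6 fell and 2 rose. Pgi fell by 0.80 ± 0.057 and the lactate dehydrogenase gene Ldh rose by 0.85 ± 0.066. Insulin, TOR and starvation genes rose in 5 of 11 and fell in 5 (list alone 5 and 5, camera adjusted p = 0.841). The insulin-like peptide gene Ilp3 rose from 23.4 ± 0.976 to 165 ± 10.9, InR rose by 1.12 ± 0.156, and Thor, a translational repressor gene, fell by 0.90 ± 0.056.

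**Figure D2:**
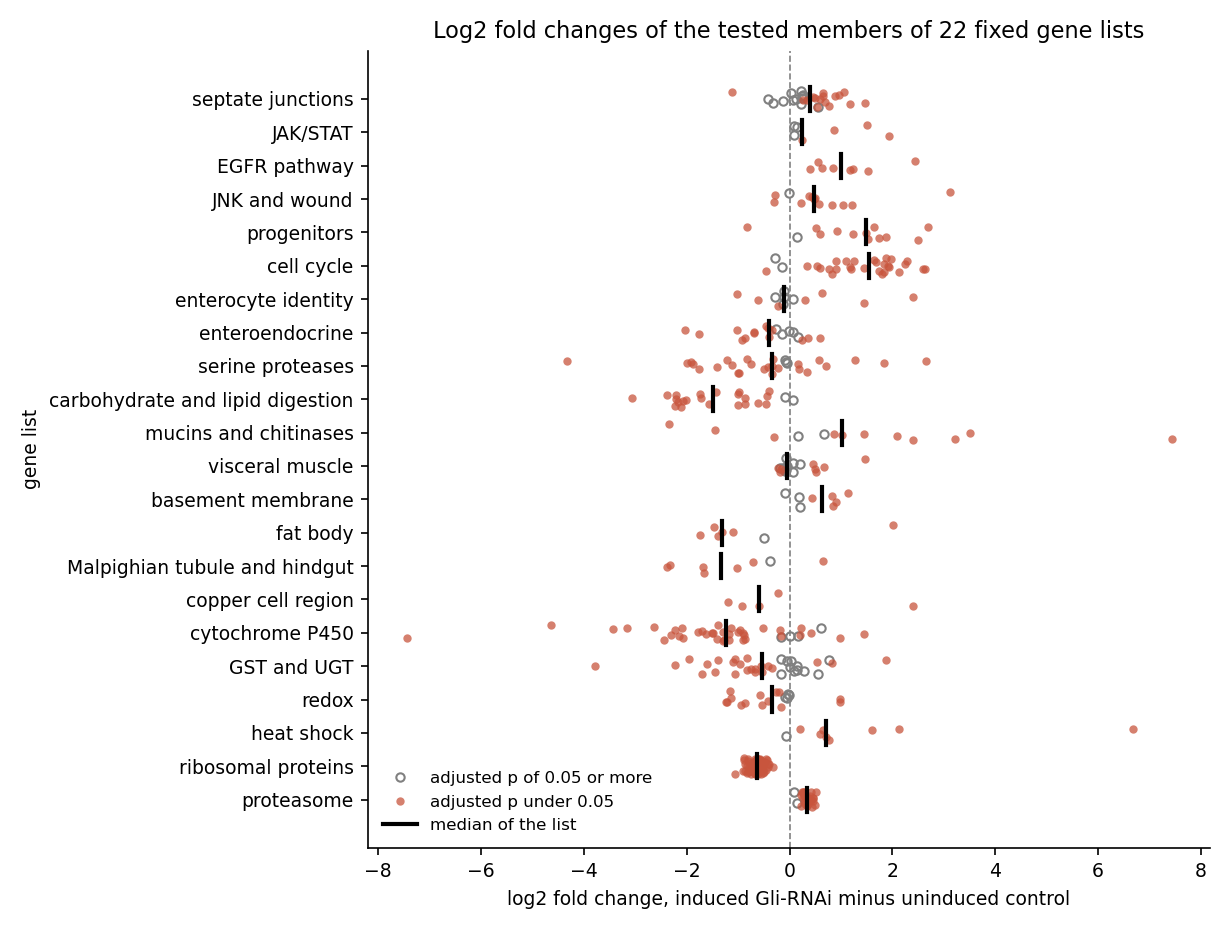
Log2 fold changes (induced minus uninduced) of the tested members of 22 of the 36 gene lists, with filled points for genes past an adjusted p of 0.05, open points for the others and a black bar at the median of each list. The medians ran from -1.4965 for carbohydrate and lipid digestion to 1.55 for the cell cycle.

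Across the 36 lists, 9 passed camera upward and 8 downward at the preset correlation, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.1005 and 11 lists had an unadjusted p under 0.05. The replicate number and the drug are further limits of this design, since each condition rests on 3 libraries and RU486 was given only to the induced flies.

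The calls were compared with the authors' deposited table. Of the genes with a fold change and an adjusted p under 0.05 in the authors' deposited table, 2727 were tested here, and 2653 of them were past the threshold in the same direction, 2029 that rose and 624 that fell. A further 3 were past the threshold in opposite directions. Log2 fold changes from the 2 sources had a Pearson correlation of 0.996 and a Spearman correlation of 0.991 across these genes, which are not independent replicates. Both sources rest on the same 6 libraries, so close values follow from the shared reads. The authors' deposited table also holds 0 genes with a log2 fold change between -1 and 0, a gap that can raise the correlations. In the authors' deposited table Gli has a mean log2 fold change of -1.14 and a smallest p of 3.1e-160. The authors' deposited table lists 2180 genes with a positive and 817 with a negative log2 fold change, where the quasi-likelihood test called 2272 and 2204.

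**Figure D3:**
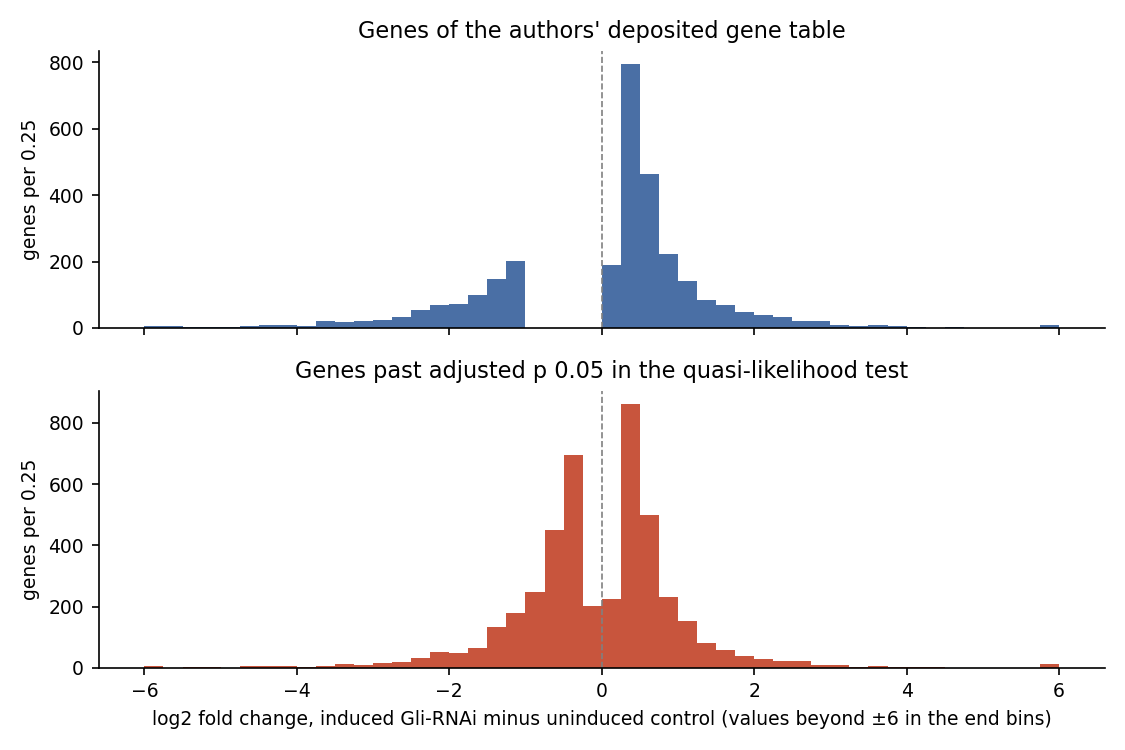
Number of genes by log2 fold change (induced minus uninduced), for the authors' deposited gene table (upper panel, 2997 genes with a value) and for the genes past an adjusted p of 0.05 in the quasi-likelihood test (lower panel, 4476 genes), with values beyond the axis placed in the end bins. The authors' table holds 0 genes between -1 and 0 and 1674 between 0 and 1.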

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

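Scaling by library totals or upper quartiles, sums over transcripts for the gene counts, and the omission of mitochondrial and shared loci were chosen after seeing the data. For the gene lists, the estimated correlation, the filter at a mean of 50 counts, the sums over transcripts and the replicate block were planned, and the other settings were chosen after seeing the data. Gli fell under every alternative run, by between 0.94 with library totals as scaling and 1.17 without control replicate 3. The count of changed genes lay between 3944 and 4958 when each library was left out in turn, the highest without control replicate 3, and was 3816 with the DESeq2 Wald test. With library totals as scaling 3737 genes rose in place of 2272, a shift set by the scaling of the same counts. Asking for an absolute log2 fold change of at least 1 left 1070 genes, 457 that rose and 613 that fell, by construction. A mean of at least 50 counts left 660 genes with at least a 2-fold change in place of 1070, with 6838 genes tested. Of the 36 lists 17 passed with a preset and 0 with an estimated correlation, and the count lay between 17 and 22 in the other settings. A higher correlation cannot account for all of the calls lost with an estimated correlation. The septate junction, JNK and redox lists lost theirs at estimated correlations of 0.009, -0.023 and 0.0044, below the preset 0.01. What else lowered the calls was not tested. The overlap with the authors' deposited table lay between 2230 genes at an adjusted p under 0.01 and 2709 with library totals as scaling. Fisher's exact test with other backgrounds and the pseudocounts were not run, since camera was used and the table holds counts.

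Of the genes open to naming, 6 that did not pass the test in the main setting were past it and higher with library totals as scaling: Jon65Aiv (0.12), alphaTry (0.14), Prx2 (0.14), MsrA (0.19), Hsc70-4 (0.13) and Vha68-2 (0.17). Calls of 6 further such genes (Ptp61F, dpy, CycB3, piwi, dve and VhaAC39-2) were lost in at least 1 setting. Replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.16, 0.05 and -0.09 across genes, and not every library correlated best with its own number. With the number as a replicate block 4281 genes changed, 2168 that rose and 2113 that fell, 1061 of them at least 2-fold, the log2 fold change of Gli was -1.13 and 19 lists passed. Small changes can be missed, since 42% of the simulated genes with the smallest change were recovered. Far fewer genes were changed in the simulation than were called in the data, which made the Benjamini-Hochberg adjustment stricter there. The simulated shares therefore do not give the sensitivity of the test on the data, and depth was not tested apart from this. Without the filter 14 of the 18 antimicrobial peptide genes were tested, and only the 2 also tested with it, Drsl2 and Drsl3, were past the threshold.

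In the 10 splits of the 6 libraries into 3 and 3, the real split gave 4476 genes and the highest of the others gave 0, but 1 of 10 splits cannot give a share under 0.05. All other splits also mix the conditions within each group. The difference between conditions then raises the spread within groups, so few calls could come from them and the contrast decides nothing.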

Other observations

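The tests on the authors' gene table and on the digestive enzymes were chosen after those results were seen, and the gene groups below were put together after seeing the data; the test on antiviral genes was written before its result was seen.

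Of 23 tested genes of actin, tubulin, myosin and their attachment sites 15 rose and 1 fell, with a median log2 fold change of 0.54. Act42A rose from 1700 ± 50.5 to 12866 ± 92.1, Act5C from 48320 ± 345 to 91771 ± 955 and betaTub60D from 500 ± 55.8 to 4318 ± 51.7, and the non-muscle myosin genes zip and sqh rose by 1.09 ± 0.078 and 1.07 ± 0.049. Of 14 secreted growth factor and related genes 10 rose and 2 fell, and Pvf1, a PDGF- and VEGF-related ligand gene, rose from 175 ± 4.73 to 1969 ± 14.5. In all, 15 genes with at least 50 normalised counts in the higher condition rose at least 16-fold by the fitted log2 fold change and 23 fell by as much.

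The authors' deposited table lists 72.7% of its 2997 genes with a fold change as higher. It holds 0 genes with a log2 fold change between -1 and 0 and 1674 between 0 and 1, and of 1559 genes that the authors' transcript table calls but the gene table leaves out, 1555 of 1556 tested here were lower, at a median of -0.45. This suggests that falling genes were kept only below -1 and rising genes at any size. Of the 4288 genes that the authors' transcript table calls and that were tested here, 2103 (49.04%) were higher with a scaling that centres the fold changes. Under such a scaling, this argues against an excess of rising genes among the authors' calls as the source of the 72.7%. Whether more genes rose in the libraries themselves stays open. With the centring scaling 50.8% of the genes called here rose, and 71.2% did with library totals, which do not centre the fold changes. No biological explanation was tested.

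If a loss of enterocytes had lowered the digestive enzymes (median -1.496), the 12 tested genes of the enterocyte identity list should have fallen about as far, but their median was -0.112, with 4 that rose and 3 that fell. The SE of their mean was 0.268. The median of the 12 was -0.1572 without control replicate 3, where 6 fell, and -0.1293 with DESeq2 size factors, where 5 fell. The list as a whole thus did not fall as far as the enzymes. Its genes did not move together, however. Their mean was 0.19, and 2 rose at least 2-fold while 1 fell as far. They may therefore not follow the number of enterocytes, and a loss of enterocytes stays open. Less copper cell tissue would have lowered lab, Vha100-4 and CAH7 at least as far as the enzymes, but their mean was -0.902 (SE 0.174 over the 3 genes); all of them fell, so a smaller loss of that tissue stays open too. With library totals as scaling 21 enzymes still fell. That switch moved the median over all genes by only 0.19 (log2), so this outcome was nearly fixed beforehand. It shows only that the choice between these 2 scalings does not account for the fall. A larger shift common to all genes could be seen with neither of them. Lower expression within enterocytes is a candidate explanation that stays open, as do an effect of RU486, a change in feeding and less hindgut, Malpighian tubule or fat body tissue in the dissections, since several of those markers fell too and were not tested as a source of the enzymes.

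The genes cGlr1, which encodes a sensor upstream of Sting, and Mov10 rose from 31.9 ± 6.56 to 553 ± 22.5 and from 405 ± 15.4 to 6450 ± 65.8. If they belonged to a wider antiviral response, the other genes of an antiviral list should have a median of at least 1. A median under 0.5 was to argue against it. The list held Sting and RNA interference genes and also genes outside these groups, among them Stat92E (0.08), vir-1 (-0.26) and ref(2)P (0.63). The median over its 14 genes was 0.436, with 9 that rose and 0 that fell, which met the bound of 0.5 as written. That median depends on which genes were listed. The SE of the mean over these genes was 0.2, so the median lay within 1 SE of that bound. This margin was not part of the prediction, and because of it no conclusion was drawn. Nazo and Srg3, both regulated by Sting, rose from 784 ± 82.7 to 4566 ± 280 and from 2307 ± 191 to 6581 ± 133, while AGO2 and Sting rose by 0.83 ± 0.051 and 0.47 ± 0.064. The loss of Gli, the double-stranded RNA made by the transgene and RU486 come together in this design, so they cannot be told apart as sources of these changes, and an RNAi against another target was not analysed here.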
